A study of Mus musculus with 4 samples.

How the data were processed

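RNA was measured in 4 libraries of primary mouse chondrocytes, 2 from floxed control mice and 2 from floxed mice with the inducible Cre, all treated with 4-hydroxytamoxifen. Groups and replicate numbers follow the sample labels. Per the labels' protocols, poly(A) RNA was captured on oligo(dT) beads and broken into fragments, and cDNA was primed at random positions. The protocol described there does not mention a strand-marking step or molecular identifiers.

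The authors deposited 1 table of raw counts, whole numbers of reads per gene symbol that are not scaled to library size, with a column per library. The submitters' processing notes name Trim Galore 0.6.7, FastQC 0.11.9, HISAT2 2.2.1, StringTie 2.1.7 and the mouse genome build mm10, with no role or order. Which tool made the counts, its strand setting, its handling of reads that match several genes, and the gene annotation are not given in the sources used here. Reads of overlapping, antisense or near-identical genes may therefore be split or assigned in ways the counts do not show. The table lists 25239 gene symbols, of which 6758 have 0 counts in all 4 libraries, and it holds no mitochondrially encoded genes, so that list, fixed as a sign of RNA quality, had no members. Gene positions come from GENCODE M21 on the same build, which holds 24366 (96.5%) of the symbols.

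Total counts were 66750140 and 77285899 in control replicates 1 and 2 and 76425194 and 78873054 in cKO replicates 1 and 2. Between 16531 and 16985 genes were above 0 per library, and the 10 highest genes took 9.36% to 11.8% of the counts. Among genes with 1 to 20 counts, 30.0% to 32.0% of values were multiples of 4, against 25.0% for evenly spread values. The reason for this excess is not given in the sources used here, and counts divided by 4 were tried as an alternative. A floor of 3 counts was used for genes at 0 in a group; such floors cover counting error only, and PCR copies of a molecule cannot be told from separate molecules.

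Genes were kept by filterByExpr in edgeR 4.0.16 (R 4.3.3; minimum count 10), which left 15522. Counts were scaled by TMM factors and tested by the edgeR quasi-likelihood test (glmQLFit and glmQLFTest) for genotype, with no covariate, and Benjamini-Hochberg adjustment over all genes tested, at a threshold of 0.05. The biological coefficient of variation was 0.174. Standard errors are the absolute log2 fold change over the square root of F, and 95% intervals use the t distribution with the total degrees of freedom. CPM values use the TMM-scaled library size, except summed marker CPM, which use the library size itself. Group values are mean ± SD of 2 libraries.

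Before the data were examined, 29 gene lists, the tests, the alternatives and the rule for naming genes were fixed. Of the lists, 28 had tested members and 27 had the 3 or more that set tests need. The lists cover Wnt targets, ligands, receptors and antagonists, cartilage matrix, hypertrophy, matrix-degrading proteases, inflammatory mediators, fibroblast, macrophage, endothelial, muscle, adipocyte, erythroid, osteoclast and Schwann cell markers. They also cover cell cycle, p53 and senescence, interferon, immediate early, unfolded protein stress, hypoxia and glycolysis, TGF-beta and BMP, hedgehog, Notch, circadian, sex-linked, mitochondrial and ribosomal protein genes. The 5 sex-linked genes gave no edgeR call (1 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom; camera adjusted p = 0.33). Their median log2 fold change was 1.00 with all libraries, 0.08 without control replicate 1 and 14.65 without control replicate 2. Sets were compared with other genes by camera (limma 3.58.1, preset correlation 0.01, log2 CPM with a prior count of 2), again with an estimated correlation, and tested for a one-way shift by fry, each adjusted over the lists. Camera gave 14 lists past 0.05 with the preset and 0 with the estimated correlation, and fry gave 2, the Wnt target and osteoclast lists. With the estimated correlation, camera uses the few residual degrees of freedom that 4 libraries leave. Its smallest unadjusted p was then 0.084, for the fibroblast list. A high adjusted p there, here and below, cannot show whether correlation between genes accounts for a shift. Lists that share a camera adjusted p of 0.51 with the estimated correlation differ before adjustment. For the Wnt targets the estimate was -0.05 (camera unadjusted p = 0.089), and for the cartilage list 0.62 (0.21). The fry test for change in either direction gave 18.

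The naming rule took Trabd2b, the 12 highest and 12 lowest log2 fold changes among called genes with a mean log2 CPM of at least 1 and groups that do not overlap, leaving out predicted gene models, and up to 4 members per list by p-value. Of the 8 genes called higher at 2-fold or more, 2 fall outside it, a predicted gene at 0 counts in controls and a RIKEN gene. Any tested Wnt target could be named. The cartilage genes Col2a1, Acan, Col11a1, Col11a2, Hapln1, Comp, Chad, Wwp2, Sox9, Prg4 and Cilp, and Slc2a1 of the hypoxia list, fall outside this rule and were chosen after their values were seen.

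The test was tried on simulated counts for the cKO against control comparison (15181 genes in the fit). It recovered 26 of 50 genes changed 1.5-fold, 60 of 97 changed 2-fold and 37 of 48 changed 4-fold, with 7 false calls among 130. Simulated genes were drawn independently, with no difference of sex or cell types between libraries, so these rates may not hold for the real calls. Replicates were compared before averaging. Pearson correlations of log2 CPM were 0.972 within controls and 0.977 within cKO, and 0.969 to 0.976 between groups. The chi-square per degree of freedom within groups was 34.0 and 37.2, or 8.51 and 9.30 after counts were divided by 4, so no library repeats another within sampling noise.

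Alternatives were RLE and upper-quartile factors, library sizes alone, DESeq2 1.42.0, limma-voom, no filter, a filter on a mean CPM of at least 1, a replicate block, leaving out each library in turn, a fold threshold of 2, and other camera settings. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.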

Results

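Gene expression was measured by RNA-seq of poly(A) RNA in primary mouse chondrocytes, the cells that make and maintain cartilage. The study asks how loss of Tiki2 (gene symbol Trabd2b), a membrane protease of the Wnt-inactivating Tiki family, changes these cells. There were 2 control libraries, from mice with floxed Tiki2 alleles, and 2 conditional knockout (cKO) libraries, from floxed mice that also carry a tamoxifen-inducible Cre under Col2a1 control. All 4 cultures received 4-hydroxytamoxifen, which activates this Cre. Only the cKO libraries carry the Cre, so an effect of the Cre itself cannot be told apart from loss of Tiki2. Total counts ranged from 66750140 in control replicate 1 to 78873054 in cKO replicate 2. Nothing in the labels says whether replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical within cKO.

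The libraries differed in the sex of the animals. Control replicate 1 had 112185 counts of Xist, the RNA that silences an X chromosome in female cells, and 0 counts of the Y-linked gene Ddx3y. The other 3 libraries had 36 to 171 Xist counts and 11073 to 12085 Ddx3y counts. The control libraries therefore did not come from 1 same animal. The library with high Xist stands alone in the control group, so no comparison of genotypes could be made within its sex. The fits without control replicate 1, given below, compare only libraries with Ddx3y counts, with 1 control library left.

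Trabd2b (ENSMUSG00000070867.4, protein-coding, mm10 chromosome 4, 114406724 to 114615098) remained expressed in the cKO cultures. Its counts were 28513 and 31314 in the controls and 22643 and 29473 in the cKO libraries. Normalised expression was 426 ± 14.6 CPM in controls and 327 ± 49.98 CPM in cKO (SD, n = 2 each), a log2 fold change of -0.38 ± 0.11 (SE). The 95% interval ran from -0.64 to -0.12, and the edgeR quasi-likelihood test gave an adjusted p of 0.15. DESeq2 gave an adjusted p of 0.0058, and edgeR without cKO replicate 2 gave 0.027 at a log2 fold change of -0.54. The counts cover the whole gene, so loss of the floxed part alone could not be read from them.

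Across the 15522 genes tested, 202 differed between genotypes (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). An unadjusted edgeR p under 0.05 was found for 2676 of the 15522, the background for the counts of such list members given below. Of these, 61 were higher and 141 lower in cKO, and changes of 2-fold or more numbered 8 upward and 51 downward. With library sizes alone in place of TMM scaling, the calls split into 116 higher and 123 lower. Without control replicate 1, 1 gene was called higher and 4 lower, without control replicate 2, 6 higher and 13 lower, and without cKO replicate 1, 312 higher and 470 lower. All 202 genes kept their direction in each of these fits. The fits reuse the libraries in which the genes were called, so kept direction is not separate support.

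Of the 12 genes that fell most under the naming rule, 2 are in the cartilage list, Snorc and Col9a2. Snorc, a chondrocyte membrane proteoglycan, fell by 1.77 ± 0.24 (log2 fold change ± SE), and Col9a2, a chain of type IX collagen, fell by 1.69 ± 0.17. Sox8, a transcription factor related to Sox9, fell by 1.64 ± 0.25. Gpr84, a receptor for medium-chain fatty acids, went from 9.70 ± 0.342 to 1.52 ± 0.335 CPM (SD, n = 2), 6.39-fold lower. Dlg2, a synaptic scaffold protein, fell by 2.17 ± 0.29, Moxd1, a monooxygenase, fell by 1.92 ± 0.17, and Atp1b2, a sodium pump subunit, fell by 1.88 ± 0.28. Azgp1, a secreted glycoprotein, fell by 1.63 ± 0.26. The remaining 4 of the 12, as the naming rule takes them, have close relatives that can share their reads, so their values are uncertain. Serpina3m fell by 1.62 ± 0.11 and Entpd4 fell by 1.65 ± 0.14. Sap18b fell by 4.05 ± 0.21, while the sum of Sap18b and Sap18 had a log2 fold change of 0.07. Zfp968 had 5.08 CPM in controls and 0 counts in both cKO libraries, at least 134-fold lower against a floor of 3 counts per library.

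The 12 largest increases among genes that the naming rule takes were smaller. Axin2, a feedback inhibitor and common readout of Wnt/β-catenin signalling, rose 2.30-fold. Olfml2a and Klhdc7a each rose by 1.23 on the log2 scale, Sarnp, an RNA-binding protein, by 1.15, and Adgrd1, an adhesion G-protein-coupled receptor, by 1.01. Cd248 (endosialin), a stromal cell surface protein, rose from 54.9 ± 5.93 to 105 ± 9.95 CPM (SD, n = 2), and Emilin2, an extracellular matrix glycoprotein, from 96.3 ± 2.70 to 178 ± 21.9 CPM. Eda2r, a p53-induced receptor, rose 1.87-fold. Piezo2, a mechanosensitive channel, rose by 0.87 ± 0.12 (log2 ± SE), Selenop, a selenium carrier, by 0.85 ± 0.12, and Gda, a guanine deaminase, by 0.78 ± 0.11. The pseudogene Pisd-ps3 rose by 1.01, with reads that its parent gene can share. Adjusted p-values of the 24 genes lay between 0.0138 for Sap18b and 0.0472 for Azgp1 (edgeR).

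**Figure D1:**
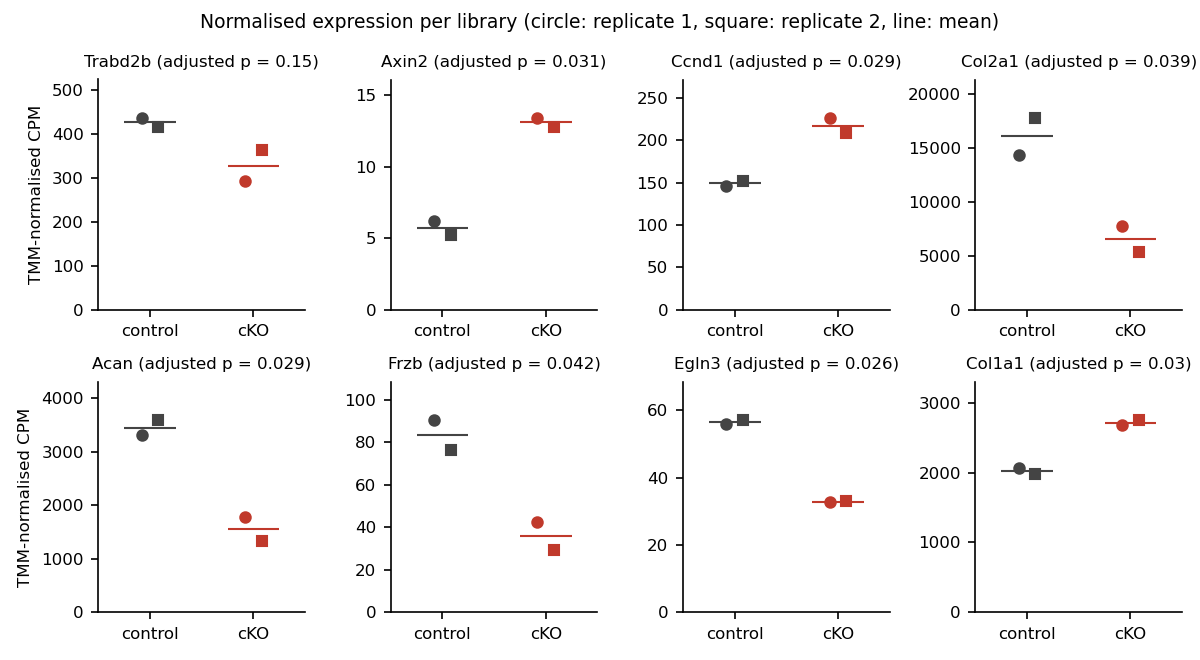
TMM-normalised expression (CPM, linear axes) of 8 genes in the 2 control and 2 cKO libraries; points are libraries and lines are group means. The groups do not overlap for any of the 8 genes, as for 7726 of the 15522 genes tested (49.8%), against 33.3% by chance in a design of 2 against 2; the rule for the largest changes required this separation.

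The series title names Wnt/β-catenin signalling as a pathway that Tiki2 inhibits. Of the 20 Wnt target genes tested, 2 rose in cKO, Axin2 and Ccnd1, and none fell. Axin2 (chromosome 11, 108920349 to 108950783) went from 5.69 ± 0.692 to 13.1 ± 0.442 CPM (SD, n = 2; edgeR adjusted p = 0.0309). Ccnd1, which encodes the cell cycle regulator cyclin D1, went from 149 ± 3.64 to 217 ± 12.7 CPM, 1.46-fold (edgeR adjusted p = 0.0289). Adjusted over the list alone, 4 members were higher, the other 2 being Fgf18 and Jag1. Fgf18, a growth factor of cartilage, had a log2 fold change of 1.63 ± 0.39 at a low level of 0.609 CPM in controls, and Jag1, a Notch ligand, of 0.45 ± 0.11. Notum (log2 fold change 0.75), Lgr5 (0.89), Nkd1 (0.56), Tcf7 (0.59), Lef1 (-0.50) and Myc (-0.22) did not pass, with edgeR adjusted p-values from 0.18 for Notum to 0.43 for Tcf7.

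As a set, the Wnt targets had a median log2 fold change of 0.33, and 14 of the 20 were above 0. The set ranked above other genes by camera with a preset correlation of 0.01 (adjusted p = 0.0129 over 27 lists). With the estimated correlation, -0.05 and so below the preset, the camera adjusted p was 0.51 (unadjusted p = 0.089). A lower correlation would not by itself raise p, and that test has few residual degrees of freedom, so it cannot decide here. The fry test for change in one direction gave an adjusted p of 0.0484. Leaving out control replicate 1, control replicate 2, cKO replicate 1 or cKO replicate 2 gave 0, 0, 3 and 1 members higher, and without control replicate 1 the median was 0.20 and the camera adjusted p 0.065. The summed expression of 8 adipocyte markers, scaled by library size, was higher in the same cKO libraries, at 202 and 204 CPM in controls and 306 and 500.0 CPM in cKO. Such sums do not measure a share of cells, and whether they bear on the Wnt targets was not tested.

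Other parts of the Wnt pathway gave a single call. Frzb, a secreted Wnt-binding protein of cartilage, went from 83.5 ± 9.78 to 36.0 ± 9.33 CPM (SD, n = 2) and fell by 1.21 ± 0.18 on the log2 scale (edgeR adjusted p = 0.0417), the only call among 10 Wnt antagonists tested. With p-values adjusted over the list alone, 5 antagonists were higher and 2 lower, the latter being Frzb and Trabd2b itself, which the list contains. Sfrp1 had a log2 fold change of 1.19 and Sfrp4 of 0.92, with edgeR adjusted p-values of 0.13 and 0.11. The list median was 0.56, opposite in sign to the single call, with a camera adjusted p of 0.0403, and an adjusted p of 0.51 with an estimated correlation. None of 10 Wnt ligands or 15 receptors passed by edgeR or when adjusted over the list alone, while 3 and 6 had an unadjusted p under 0.05, DESeq2 called 1 and 2, and limma-voom 0. The ligand median was 0.37 (camera adjusted p = 0.0292, and adjusted p = 0.51 with an estimated correlation) and the receptor median 0.17 (camera adjusted p = 0.0528). Frzb did not pass without control replicate 1 or without control replicate 2, 3 antagonists were called higher without cKO replicate 1, and 2 were called lower without cKO replicate 2. The camera adjusted p of the ligands was 0.0843 without control replicate 2 and 0.0509 without cKO replicate 2, and that of the antagonists was 0.0878, 0.081 and 0.124 without control replicate 2, cKO replicate 1 and cKO replicate 2. With library sizes alone it was 0.101 for the antagonists and 0.0665 for the ligands, and for the receptors it was 0.0341 without control replicate 2. The ligand median was 0.56 without control replicate 1 and the antagonist median 0.37 without control replicate 2. The adipocyte sums given above were higher in the same cKO libraries.

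Of 26 cartilage matrix and chondrocyte identity genes, 13 fell and none rose. Col2a1, which encodes the main cartilage collagen (chromosome 15, 97975602 to 98004695), went from 16056 ± 2409 to 6587 ± 1705 CPM (SD, n = 2), 2.44-fold lower in cKO. Acan, which encodes the proteoglycan aggrecan, was 2.22-fold lower, from 3444 ± 194 to 1549.7 ± 315 CPM. The other 11 were the type IX collagen genes Col9a1, Col9a2 and Col9a3, the type XI collagen genes Col11a1 and Col11a2, and Matn1, Hapln1, Comp, Chad, Snorc and Wwp2, with log2 fold changes between -1.77 for Snorc and -0.78 for Col11a1. Sox9, the master transcription factor of chondrocytes, had a log2 fold change of -0.38 ± 0.11 (edgeR adjusted p = 0.15), and Prg4, which encodes the lubricin of superficial cartilage, of 0.23 ± 0.09 (adjusted p = 0.25). Adjusted over the list alone, 21 were lower and 2, Prg4 and Cilp, higher.

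The cartilage list median was -0.94, with a camera adjusted p of 1.0e-09, and an adjusted p of 0.51 with an estimated correlation. The fry test gave an adjusted p of 0.13. In the same libraries the summed expression of 8 adipocyte markers was 202 and 204 CPM in controls and 306 and 500.0 CPM in cKO, scaled by library size. Without control replicate 1 and without control replicate 2, 1 cartilage gene passed in each fit, while 23 of the 26 stayed below 0 in both.

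**Figure D2:**
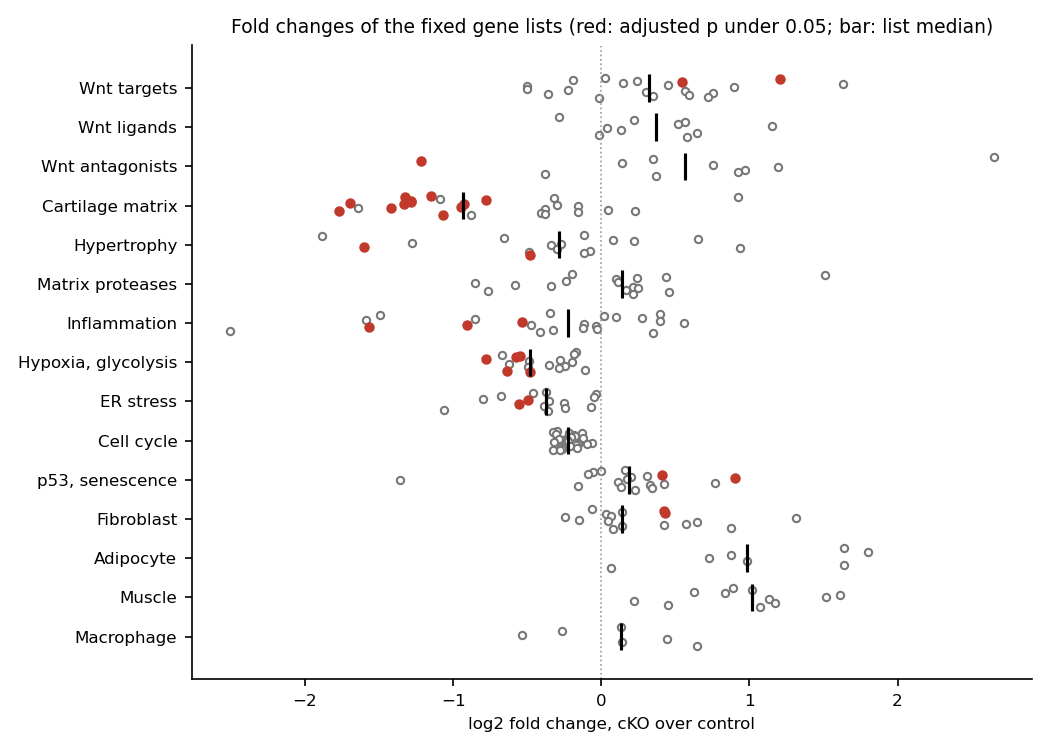
Log2 fold change (cKO over control) of each tested member of 15 gene lists, with members past an edgeR adjusted p of 0.05 in red and list medians as bars. The cartilage matrix list has 13 red members, all below 0, and the Wnt target list 2, both above 0.

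Genes of chondrocyte hypertrophy and of matrix breakdown, processes of osteoarthritic cartilage, gave few calls. Of 16 hypertrophy and mineralisation genes 2 fell and none rose. Panx3, a channel of hypertrophic chondrocytes, fell by 1.60 ± 0.15 (log2 ± SE), and Vegfa, an angiogenic factor, fell by 0.48 ± 0.07. The same 2 genes were lower when adjusted over the list alone, and the camera adjusted p was 0.0531, or 0.0226 with library sizes alone, 0.0158 without cKO replicate 1 and 0.51 with an estimated correlation. Col10a1 had a log2 fold change of -0.66 ± 0.20 and Mmp13 of -0.34 ± 0.10, with edgeR adjusted p-values of 0.18 and 0.15. None of 16 matrix-degrading proteases passed by edgeR, 10 had an unadjusted p under 0.05, DESeq2 called 2 higher and 3 lower, and limma-voom called 1 lower. There were 2 proteases higher and 4 lower when adjusted over the list alone. Mmp3 was at -0.76 ± 0.14 (edgeR adjusted p = 0.0642) and Adamts15 at 1.51 ± 0.30 (0.0745), and the camera adjusted p of the list was 0.62. Leaving out control replicate 1, control replicate 2 or cKO replicate 1 gave 0, 0 and 4 hypertrophy genes lower, and without cKO replicate 1, 3 proteases were higher and 2 lower. In the same libraries the adipocyte sums were 202 and 204 CPM in controls and 306 and 500.0 CPM in cKO.

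Of 22 inflammatory mediators 3 fell and none rose. Nos2, the inducible nitric oxide synthase, fell by 1.57 ± 0.22 (log2 ± SE), Lcn2, an acute-phase iron-sequestering protein, fell by 0.90 ± 0.11, and Icam1, a leukocyte adhesion molecule, fell by 0.54 ± 0.06. The chemokine gene Cxcl1 was at -0.85 ± 0.15 (edgeR adjusted p = 0.0642). Adjusted over the list alone, 9 were lower and 3 higher. The camera adjusted p was 0.0242, with an adjusted p of 0.59 under an estimated correlation. The list median was -0.22, and 0.02 without control replicate 1, with 11 of 22 above 0, and -0.36 without control replicate 2. Without control replicate 1 no mediator passed and the camera adjusted p was 0.57, without cKO replicate 1, 5 were lower, and without cKO replicate 2 the camera adjusted p was 0.0505. The summed adipocyte markers, 202 and 204 CPM in controls and 306 and 500.0 CPM in cKO, changed in the same libraries.

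Of 17 hypoxia and glycolysis genes 5 fell and none rose, and all 17 fold changes were below 0, with library sizes alone as well. The 5 were Egln3, an oxygen-sensing prolyl hydroxylase (56.4 ± 0.778 to 32.9 ± 0.275 CPM, SD, n = 2), the glucose transporter Slc2a1, the carbonic anhydrase Car9, the mitophagy receptor Bnip3, and Vegfa. Their log2 fold changes ran from -0.78 for Egln3 to -0.48 for Vegfa, and 15 were lower when adjusted over the list alone. Of 15 genes of the unfolded protein and amino acid stress response 2 fell, the chaperone genes Hspa5 (919 ± 13.0 to 626 ± 33.0 CPM) and Dnajb9 (93.8 ± 0.519 to 66.7 ± 1.24 CPM). All 15 were below 0 with TMM scaling and 13 with library sizes alone, and 10 were lower when adjusted over the list alone. Camera gave an adjusted p of 1.4e-09 for the hypoxia list and 5.9e-06 for the stress list, and the adjusted p was 0.51 for each with an estimated correlation. Leaving out control replicate 1, control replicate 2, cKO replicate 1 or cKO replicate 2 gave hypoxia medians of -0.44, -0.42, -0.53 and -0.36. The stress medians were -0.42, -0.35, -0.48 and -0.25 in that order. All 17 hypoxia and all 15 stress genes stayed below 0 in each of these fits. The fits reuse the same libraries, so kept direction is not separate support. The adipocyte sums, 202 and 204 CPM in controls and 306 and 500.0 CPM in cKO, differed in the same libraries.

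Of 16 fibroblast and dedifferentiation markers 2 rose, the fibrillar collagen genes Col1a1 (2023 ± 54.3 to 2709.7 ± 51.1 CPM, SD, n = 2) and Col3a1 (2543 ± 79.9 to 3433 ± 152 CPM), and none fell. Thy1 (log2 fold change 0.88) and Dpt (1.31) had edgeR adjusted p-values of 0.0571 and 0.0605, and adjusted over the list alone 7 markers were higher and 1 lower. The summed adipocyte markers, at 202 and 204 CPM in controls and 306 and 500.0 CPM in cKO, were higher in the same libraries. Of 18 p53 and senescence genes 2 rose, Eda2r and the cyclin gene Ccng1 (log2 fold change 0.41 ± 0.06), and none fell. Adjusted over the list alone, 6 of these were higher and 1 lower. Camera gave an adjusted p of 0.00900 for the fibroblast list and 0.00518 for the p53 list, and the adjusted p was 0.51 for each with an estimated correlation. No member of either list passed without control replicate 1 or without control replicate 2, and 7 fibroblast markers were higher and 3 lower without cKO replicate 1. Without that library the camera adjusted p was 0.081 for the fibroblast and 0.159 for the p53 list.

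None of the 24 cell cycle genes passed by edgeR, 7 had an unadjusted p under 0.05, DESeq2 called 1 lower and limma-voom 0. All 24 were below 0 with TMM scaling, 23 with library sizes alone and 19 without control replicate 2, and the median was -0.22, -0.35 without control replicate 1 and -0.06 without control replicate 2. Camera gave an adjusted p of 0.00013, with an adjusted p of 0.59 under an estimated correlation, and 0.055 without control replicate 2. These libraries also differed in the adipocyte sums, 202 and 204 CPM in controls and 306 and 500.0 CPM in cKO. Of 14 immediate early genes 1 fell, Ier3, a stress-response gene that fell by 0.93 ± 0.11 (log2 ± SE). Of 14 circadian clock genes 1 fell, the clock repressor gene Bhlhe41, which fell by 0.55 ± 0.08 and did not pass with library sizes alone. Adjusted over each list alone, 2 and 4 genes were lower, and neither gene passed without control replicate 1 or without control replicate 2. Without cKO replicate 1 there were 3 and 2 calls, and without cKO replicate 2, 2 and 0. The camera adjusted p was 0.92 and 0.12.

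No member of the interferon response, TGF-beta and BMP response, hedgehog or Notch lists passed by edgeR. The 24 interferon genes had a median of 0.03 and 2 members at an unadjusted p under 0.05, and DESeq2 called 1 and limma-voom 0. Their median turned to -0.36 without control replicate 1, with 19 of 24 below 0 (camera adjusted p = 3.0e-04), and was 0.52 without control replicate 2, with all 24 above 0 (1.3e-08). The 15 TGF-beta and BMP genes had a median of -0.12 and 7 such members, and DESeq2 called 3 and limma-voom 1. The 8 hedgehog genes had a median of -0.06, which lay above 0 with library sizes alone, and 1 such member, with 0 calls by DESeq2 and limma-voom. The 7 Notch genes had a median of 0.16 and 4 such members, and DESeq2 called 3 and limma-voom 0. The TGF-beta and BMP median was -0.05 with library sizes alone and -0.07 without cKO replicate 2, the hedgehog median -0.005 without cKO replicate 1, and the Notch median 0.10 without control replicate 2 and without cKO replicate 1. Adjusted over each list alone, 4 TGF-beta and BMP genes were higher and 2 lower, 3 Notch genes were higher and 1 lower, and no interferon or hedgehog gene passed. Camera adjusted p-values were 0.24, 0.35, 0.83 and 0.0874 in that order.

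Apart from the fibroblast list, markers of other cell types that a chondrocyte preparation could hold gave no edgeR call. The 7 adipocyte markers tested had a median log2 fold change of 0.98, with Lpl at 0.98 ± 0.20 (SE; edgeR adjusted p = 0.0782), Cfd at 1.80 ± 0.36 (0.0785) and Adipoq at 1.64 ± 0.38 (0.10). Adjusted over the list alone 5 were higher, the same number had an unadjusted p under 0.05, DESeq2 called 4 and limma-voom 0. Their camera adjusted p was 0.00531, with an adjusted p of 0.58 under an estimated correlation. Lpl alone was at 105 ± 7.05 CPM in controls and 207 ± 64.3 CPM in cKO (SD, n = 2). Adipoq was at 5.39 ± 1.77 and 16.8 ± 8.20 CPM. The summed adipocyte markers given beside other lists do not measure the share of fat-like cells. Leaving out cKO replicate 1 or cKO replicate 2 gave 5 and 1 adipocyte markers higher, and without cKO replicate 2 the median was 0.62.

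The 11 skeletal muscle markers had a median of 1.02, but their summed CPM of 6.02 and 45.5 in controls and 97.7 and 17.7 in cKO did not separate the groups. Leaving out control replicate 1, control replicate 2, cKO replicate 1 or cKO replicate 2 gave muscle medians of 0.19, 5.64, -0.73 and 1.86, all 11 markers were below 0 without cKO replicate 1, and the camera adjusted p was 0.00063 without control replicate 2 and 0.0271 without cKO replicate 2. The 6 macrophage and leukocyte markers had a median of 0.14 and sums between 20.5 and 27.6 CPM, the 4 endothelial markers a median of -0.03, above 0 with library sizes alone, and the 1 erythroid gene tested a value of 0.67. Without control replicate 2 and without cKO replicate 2 the macrophage median was -0.14 and -0.09 and the endothelial median -0.17 and -0.36. Without control replicate 1 and without cKO replicate 1 they were 0.27 in both fits for macrophage and 0.25 and 0.24 for endothelial markers, and the erythroid gene was at 1.31 without cKO replicate 1 and -0.53 without cKO replicate 2. In these 4 lists no member had an unadjusted p under 0.05 or passed by DESeq2, limma-voom or when adjusted over the list alone, and the camera adjusted p was 0.12 for muscle, 0.77 for macrophage and 0.92 for endothelial markers. The 6 osteoclast markers had a median of -0.25 and 2 members at an unadjusted p under 0.05, and DESeq2 called 1 and limma-voom 0. The 4 Schwann cell and glial markers had a median of -0.71 and 3 such members, and DESeq2 and limma-voom called 1 each. They include S100b (-0.90 ± 0.15, edgeR adjusted p = 0.0577), which chondrocytes also express. The camera adjusted p was 0.0497 for each of these 2 lists, with an adjusted p of 0.51 under an estimated correlation, and 2 and 3 markers were lower when adjusted over the list alone. The fry adjusted p of the osteoclast list was 0.0364, and its median was -0.09 without control replicate 2, -0.38 without cKO replicate 1 and -0.44 without cKO replicate 2. Without control replicate 2 the camera adjusted p was 0.0878 for osteoclast and 0.315 for Schwann cell markers, without cKO replicate 1, 0.167 and 0.144, and without control replicate 1 it was 0.129 for osteoclast and without cKO replicate 2, 0.103 for Schwann cell markers. The 85 ribosomal protein genes had a median of -0.11, with 73 below 0, or -0.05 and 67 with library sizes alone, and -0.07 without control replicate 1. None passed by edgeR or when adjusted over the list alone, DESeq2 called 3 lower and limma-voom 0. An unadjusted edgeR p under 0.05 was found for 20 of the 85, against 2676 of all 15522 genes tested. Their camera adjusted p was 5.9e-06, with an adjusted p of 0.59 under an estimated correlation.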

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

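Counts divided by 4, X and Y genes left out, and the crossed pairing were chosen after the data were seen; the other alternatives were fixed before. Of the 202 called genes, all kept their direction under each alternative, except that 195 were tested with X and Y genes left out. Called genes were chosen for their difference in these same libraries, so kept direction here and below is not separate support. The 1099 calls of DESeq2 and the 307 of the stricter filter held all 202, the 333 of limma-voom held 201, and the 239 with library sizes alone held 183. The 61 genes higher in cKO became 116 with library sizes alone, 493 with DESeq2, 106 with limma-voom, 105 with the stricter filter, 128 with counts divided by 4, and 8 at 2-fold or more. The 141 lower became 606 with DESeq2, 227 with limma-voom, 243 with counts divided by 4, and 51 at 2-fold or more. Leaving out 1 library moved the higher count between 1 and 312 and the lower count between 4 and 470; a group left with 1 library is assumed to vary like the other. Without control replicate 1 there were 5 calls, 3 of them shared with the 202, and without control replicate 2 there were 19, 10 of them shared; without cKO replicate 1 there were 782, 200 shared, and without cKO replicate 2 there were 159, 124 shared. Apart from the fewer libraries, the cause of these moves was not tested. Trabd2b had a log2 fold change of -0.38 with DESeq2 (adjusted p = 0.0058), and between -0.54 (without cKO replicate 2, adjusted p = 0.027) and -0.23 when a library was left out; its adjusted p ranged from 0.0058 to 0.38 over the alternatives. The 2 Wnt targets called higher became 4 with DESeq2 and 0 to 3 when a library was left out, and the 13 cartilage genes called lower became 1 to 18. The camera adjusted p of the Wnt targets was 0.51 with an estimated correlation and 0.016 to 0.065 when a library was left out, and that of the cartilage list was 0.51 and 4.5e-11 to 1.1e-06. The interferon list changed direction without control replicate 1 (camera adjusted p = 3.0e-04), within a range of 1.3e-08 to 0.51 when a library was left out, and Xist went from a fold change below 0 to 1.67 without that library, within a range of -10.13 to 1.67. Of the 74 named genes that passed, 1035 alternative values all kept direction and 821 kept the call; 93 named genes that did not pass gave 1280 alternative values, of which 107 passed and 16 changed sign, in 12 genes. Besides Xist, ranges when a library was left out were -0.080 to 2.32 for Acta1, -0.30 to 5.64 for Myh3, -0.89 to 11.21 for Myh8, -0.39 to 3.54 for Mylpf, -0.53 to 1.31 for Alas2, -0.54 to 0.059 for Cd68, -1.21 to 0.31 for Cxcl10, -0.24 to 0.22 for Egfl7, -0.48 to 0.37 for Esam, -0.40 to 0.16 for Gli2 and -1.72 to 0.12 for Kdr; Esam was at 0.0013 with library sizes alone. Genes of 8 lists, these 11 among them, were first left out of this tally after their values were seen, and were then put back. No scaling moved the median of all genes by more than 0.065 on the log2 scale.

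The labels share replicate numbers between groups but do not say that they pair the libraries. Deviations of same-numbered libraries correlated at -0.12. With a replicate block, 3 genes were higher and 20 lower (22 of these 23 shared with the 202), 0 Wnt targets were higher and 2 cartilage genes lower, the camera adjusted p was 0.0308 for hypertrophy and 0.0686 each for osteoclast and Schwann cell markers, and Egfl7 was at -0.0017. With the crossed pairing, 223 were higher and 341 lower. Depth was similar in all libraries, and 3 counts are 0.0459 TMM-scaled CPM in the shallowest library.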

Other observations

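All tests in this part were chosen after the result was seen, except those of replicate spread in ribosomal protein genes and of the imprinted set, whose predictions were written before. The genes named in the next 2 paragraphs were chosen after their values were seen.

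Some called genes fall outside the lists, and no list or enrichment test was run on them. The protease inhibitor gene Serpina3n went from 3745 ± 125 to 1496 ± 170.3 CPM (SD, n = 2), a value its close relatives make uncertain, and Chil1, which encodes a chitinase-like protein of inflamed cartilage, from 2362 ± 291 to 1006 ± 132 CPM. A2m fell by 1.49 ± 0.14 (log2 ± SE), Lbp fell by 0.88 ± 0.12 and Cp, which encodes the copper-carrying ferroxidase ceruloplasmin, fell by 0.51 ± 0.07. The metallothionein genes Mt1 and Mt2 fell by 0.83 and 0.83, and the zinc and iron importer gene Slc39a14 fell by 0.44. Tfrc, the transferrin receptor gene, fell by 0.53 and Fth1, the ferritin heavy chain gene, fell by 0.52, while Slc40a1, which encodes the iron exporter ferroportin, rose by 0.58 ± 0.07. Adjusted p-values of these 11 genes were between 0.0143 and 0.0392 (edgeR).

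Papss2, which encodes an enzyme that makes the sulfate donor of cartilage proteoglycans, fell by 1.06 ± 0.14. The sterol synthesis genes Sqle and Msmo1 fell by 0.49 and 0.45. Cd34 rose by 0.69 ± 0.07, the matricellular gene Thbs2 by 0.73 ± 0.07 and Igfbp3 by 0.62 ± 0.06. Of imprinted genes, Peg3 fell by 0.47 ± 0.05, its neighbours Usp29 and Zim1 fell by 0.95 and 0.65, and Plagl1 fell by 0.45.

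A hypothesis from these 4 genes was that imprinted genes may fall as a set in cKO. The 27 other imprinted genes tested had a median log2 fold change of -0.02, none was called by edgeR, and fry gave a one-way p of 0.47, so the set gave no sign of a shared fall.

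The fall of cartilage matrix genes could come from the female-type control library, from a lower share of chondrocytes, or from the genotype, among other causes. A difference of litter or culture day between the groups could not be told apart from the genotype here. The tables argue against the library as the whole cause: without it the list median was -1.05, against -0.94 with all libraries, and 23 members lay below 0. Whether a loss of chondrocytes raised every other cell type alike could not be decided. Adipocyte markers (mean log2 fold change 1.10) and macrophage markers (0.09) moved apart (exact two-sided permutation p = 0.0093 over 1716 permutations of genes). The permuted genes are not independent and are not replicate cultures, so this p does not speak for the cultures. The macrophage median also ran from -0.14 without control replicate 2 to 0.27 without cKO replicate 1. More fibroblast-like or fat-like cells in the cKO cultures stays open, with medians of 0.98 for adipocyte and 0.14 for fibroblast markers, or 0.62 and 0.25 without cKO replicate 2, and the 2 fibroblast markers called are collagen genes that dedifferentiated chondrocytes also express. An effect of the genotype on chondrocytes stays open too, whether from loss of Tiki2 or from the Cre that only the cKO libraries carry.

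Trabd2b kept most of its counts in cKO after 4-hydroxytamoxifen, and recombination was not measured here. Reads from exons outside the deleted part, and cells in which no recombination took place, are candidate explanations. Neither can be told apart from the other here, since the counts cover the whole gene, and counts per exon or per cell were not used. The 95% interval of the log2 fold change, -0.64 to -0.12, shows only that most counts were kept. It does not bear on which explanation holds.

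Genes with near-identical copies gave large or erratic differences. For Sap18b, reads may have moved to Sap18, since the sum of both had a log2 fold change of 0.07 (95% interval -0.10 to 0.23). The sum of Entpd4 and Entpd4b still fell by 0.86 (interval -1.03 to -0.68, edgeR adjusted p = 0.026), which argues against such a move as the whole cause there. Gapdh, with many pseudogenes, had counts of 13382 and 3605 in controls and 5490 and 19619 in cKO, and Rpl26 had 379, 356, 471 and 11026. Ribosomal protein genes as a class did not vary more between replicates, as their median within-group difference lay at percentile 45.7 of 10000 matched lists.

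The 4 libraries can be split 2 against 2 in 3 ways, too few for a share under 0.05. The real split called 202 genes, the highest other split 0, and 1 of the 3 reached 202.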
